A study of Mus musculus with 2 samples.

How the data were processed

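The samples were 2 DNase-seq libraries from thymus tissue of female mice of the hybrid strain B6CASTF1/J aged 10 days, numbered biological replicates 1 and 2 in the labels. The labels number the females separately and give both samples the same donor identifier, so that the spread between the replicates was read as that between 2 animals of 1 genetic background. With 1 group and no control, the values were compared between replicates and with random expectation, and tests over genes, peaks or footprints describe these libraries, since none of these are replicates.

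Each library came with a pair of peak files, a list of footprints and a list of false discovery rates (FDR) of the cut rate, all on mm10 (GRCm38), per the README deposited with each sample. Peaks were deposited per library, made from its own alignments together with further input files of the same project, per that README, and were not pooled over replicates. The authors' signal in the peak files is the height of each peak. In either library 100% of the deposited signal values were whole multiples of a single step (tolerance 0.05 of a step), so that a single scaling factor was applied per library. The definition of that factor, the aligner, the peak and footprint callers, their versions and thresholds, and the number of reads were not given in the sources used here. The median height was 108 steps in replicate 1 and 143 in replicate 2. The deposited FDR values, of the p-value or q-value kind, lay under 0.05 and covered 55.2 and 24.1 Mb. The footprint list carried the constant value 0.01, read here as the FDR threshold of the call by the authors. DNase I prefers certain sequences, and whether the deposited footprints were corrected for that preference was not given in the sources used here. The mice carry 1 CAST/EiJ set of chromosomes. Reads of that set that differ from the reference may have been placed less often, which was not measured here.

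The design named the peak file with the smaller median width as the main set where the README called neither of them hotspots. Both medians were 200 bp, so the larger file, with the smaller mean width (230 and 206 bp), was taken. The other file held 93790 and 46467 peaks and served as the stricter alternative. Of these, 97.7% and 98.7% shared at least 1 bp with main peaks, and each of the stricter peaks held an FDR of at most 0.001. Genes and transcription starts were taken from GENCODE M21 for 21938 protein-coding genes, and sequence from the GRCm38.p6 assembly, after chromosome names and lengths were compared with the files. Coordinates are 1-based.

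Peaks of a library that overlapped each other were each counted, distal peaks included, and covered length counts each base 1 time. Overlap was counted from 1 bp. Random overlap was estimated from 100 circular shifts within chromosomes, and for footprints within the joined shared peaks. Heights of overlapping peaks were correlated on the log2 scale without a p-value. Peak midpoints were classed by protein-coding genes alone as promoter (within 1 kb of a transcription start), exon, intron or intergenic. Intergenic sequence may therefore hold genes of other kinds. A gene had a promoter peak where a peak lay within 500 bp of any of its transcription starts. Distal peaks lay over 1 kb from any protein-coding transcription start and were assigned to the nearest one within 100 kb. The 17 lists held 279 annotated genes, and 1 further symbol (Ahsp) was not annotated. Promoter peaks of lists were compared with all other genes by the two-sided Fisher's exact test, and distal peaks by two-sided permutation against 10000 random lists matched on 10 bins of territory length, each per replicate with Benjamini-Hochberg adjustment over the lists. A list was called where the adjusted p was under 0.05 in the same direction in both replicates. For promoter peaks seen in the replicate with more peaks alone, members were compared with other genes by the two-sided Fisher's exact test over genes with a promoter peak in that replicate. Footprints extended by 5 bp per side were searched on both strands for 21 consensus sequences. Controls were segments of the same length from the same peaks outside footprints, 1 per footprint, for 276896 and 157683 footprints. Odds ratios were taken after 0.5 was added to each count. A motif was called under the same rule where its odds ratio also lay beyond those of 20 shuffled versions of the consensus.

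The lists, consensus sequences, tests, main alternatives and the rule for named genes were fixed before the data were examined. The rule took, per list, up to 4 members with the highest mean promoter height over the library's median and up to 3 members without a promoter peak. It added the 20 genes with the most shared distal peaks, the 10 highest peaks in both replicates and a fixed set of genes that included Cd3e, Cd4, Cd8a, Rag1, Rag2, Bcl11b, Tcf7, Foxn1, Gata1 and Alb. The values of 3 genes that the rule named are not reported here. The height used for a gene is that of its highest promoter peak. Heights over the median depend on which peaks were called in a library, so their SD is not the spread between animals alone.

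The comparisons of lists, overlap and motifs were tested on simulated data, those of promoter peaks seen in replicate 1 alone and of footprint overlap only after their results were seen. Over 21938 genes, a list raised to 98% of members with promoter peaks was called in 97% of 100 simulations, a list lowered to 5% in 100%, and unchanged lists in 0%. For distal peaks, a list raised by a factor of 2, 4 or 8 was called in 0%, 65% and 100% of 40 simulations each, against 2000 random lists, and unchanged lists in 0%, so a difference of a factor of 2 in a list would have been missed in that setting. Both kinds of simulation drew the genes of each replicate independently. In the data, 12547 of the 12679 genes with a promoter peak in replicate 2 also had one in replicate 1. The shares called, that of unchanged lists included, therefore hold for independent replicates and may differ for these libraries. For promoter peaks seen in replicate 1 alone, over 13904 genes, the fibroblast list raised to 30%, 60% or 90% of members was called in 6%, 70% and 100% of 200 simulations each, and unchanged lists in 0.133%. A T-lineage list lowered to 0% was called in 0%, so a list with fewer such genes would have been missed. For the peak overlap, 60.3% of 50000 simulated intervals were copied and 60.3% were found shared. For the footprint overlap, 59.8% of 60000 simulated footprints were copied and 59.8% were found shared, and an unrelated set gave 19.7%, against 19% after circular shifts. For motifs, the CTCF consensus was put into 1.86% and 1.96% of 20000 simulated footprints per library and found in the same shares, 1 motif was called and 0 others.

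The alternatives were the upper part of the peaks by height, the stricter peak file, equal peak numbers (the 69798 highest of each replicate), reciprocal overlap of 50%, other promoter windows and assignment distances, random lists without matching, CpG-poor promoters (observed over expected CpG under 0.6), autosomes alone, other footprint settings, and each replicate left out in turn. Windows with runs of low peaks, and CpG-poor promoters for the comparison of promoter peaks seen in replicate 1 alone, were added after the data were seen. Sequence matches between places in the genome were searched with blastn 2.17.0 at 90% identity over 80% of the length. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Cut counts per base and alignments were not used here, and allele-specific signal was not analysed here.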

Results

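Open chromatin was mapped by DNase-seq in the thymus of 10-day-old female mice, F1 hybrids of the C57BL/6J and CAST/EiJ strains. DNase-seq reads the places where the enzyme DNase I cuts DNA in nuclei, and regions cut more than their surroundings are listed as peaks. The 2 libraries, from separately numbered females, formed 1 group of biological replicates without a treated or control group. Replicate 1 had 132737 peaks over 29.5 Mb and replicate 2 had 69798 peaks over 14.1 Mb, a mean of 101268 ± 44505 (SD, n = 2). Of these, 5.14% and 3.16% overlapped another peak of the same library, and joined they formed 128008 and 68292 regions. The deposited peak heights were whole multiples of one step within each library, and the steps of the libraries had a ratio of 1.00. The number of sequenced reads was not read from the files, so no counting interval is given for any share.

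The first question was how far the thymuses of the 2 animals gave the same accessible regions. Of the replicate 1 peaks, 57361 (43.2%) were overlapped by a replicate 2 peak, and of the replicate 2 peaks, 58045 (83.2%) were overlapped by a replicate 1 peak. The highest peaks were found in both animals, with 99.3% of the highest 10% of replicate 1 peaks found in replicate 2 and 99.5% of the highest 10% of replicate 2 peaks found in replicate 1. In the lowest 10% these shares were 2.32% and 34.3%. With the 69798 highest peaks of each replicate, the overlapped shares were 73.5% and 74.7%. Circular shifts of the peaks within chromosomes gave at most 1.33% and 2.64% overlap in 100 draws. Over 60801 overlapping pairs, the heights had a Pearson r of 0.896 on the log2 scale and a Spearman rho of 0.887, a description across peaks, which are not independent replicates. Distal peaks seen in replicate 1 alone had a median GC content of 47.5% against 51.5% in shared distal peaks. At equal height, the GC-richest 20% of distal replicate 1 peaks were found in replicate 2 more often than the GC-poorest 20%.

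**Figure D1:**
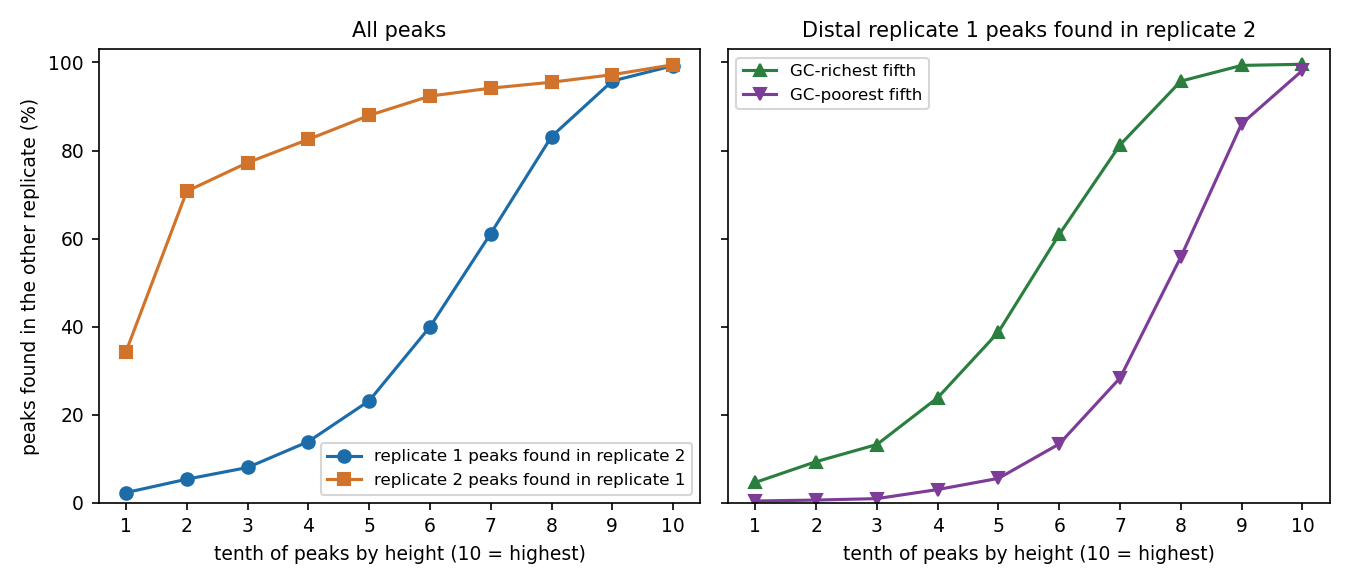
Share of the peaks of one replicate that were found in the other (%, vertical axis) in 10 equal bins of its peaks by height (horizontal axis, 10 is highest), for all peaks (left) and for the GC-richest and GC-poorest 20% of distal replicate 1 peaks (right). In height bin 7 of the distal replicate 1 peaks, 81.3% of the GC-richest and 28.4% of the GC-poorest peaks were found in replicate 2.

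Peaks were concentrated at gene starts. Promoters, the sequence within 1 kb of a transcription start, made up 3.70% of the genome and held 24.6% of replicate 1 peaks and 37.9% of replicate 2 peaks (mean 31.3% ± 9.42, SD, n = 2). Intergenic sequence, 60.1% of the genome, held 37.2% and 31.8% of the peaks, and introns, 33.6% of the genome, held 34.3% and 26.0%. Of the peaks seen in replicate 1 alone, 14.5% lay in promoters, against 38% of those seen in replicate 2 alone and 37.9% of the replicate 1 peaks shared with replicate 2. No test was run on these shares. The promoter share of all replicate 2 peaks was over 1.5 times that of all replicate 1 peaks. With equal peak numbers the gap was smaller, at 32.3% in replicate 1 and 37.9% in replicate 2.

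The highest peaks in both animals included the promoter of Dynlt1b, a dynein light chain, at chromosome 17, 6430001 to 6430180 (mm10), with heights of 47.6 and 47.8. That of Dnpep, an aminopeptidase, lay at chromosome 1, 75317461 to 75317940, with heights of 21.6 and 31.0. Other promoters among the highest 10 were those of Mplkip (chromosome 13, 17694901 to 17695120), Fzr1, a cell cycle regulator (chromosome 10, 81378541 to 81378780), and Ing2 (chromosome 8, 47675081 to 47675320). Further peaks lay within the gene Cers5 on chromosome 15 (99735641 to 99736080) and within the gene Mid1 on the X chromosome (169997981 to 169998240 and 169998261 to 169998420). The remaining peaks lay 35530 bp from the start of Pak3 on the X chromosome (143482981 to 143483140) and on chromosome 17 (39846781 to 39846920). The latter lay outside protein-coding genes, and genes of other kinds were not looked up there. The sequences of 4 of the 10 peaks matched at least 1 other place in the genome at 90% identity over 80% of their length. These lay at Dynlt1b, at both places in Mid1 and at chromosome 17, 39846781 to 39846920.

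Which gene groups had open promoters in the thymus was asked with 17 gene lists fixed beforehand. Genes of the T-cell receptor complex and its proximal signalling had a peak within 500 bp of a transcription start in 20 of 20 members in both replicates. The highest of these was at Cd8b1, a chain of the CD8 coreceptor (chromosome 6, 71322788 to 71337494), with a height 11 ± 0.15 times the library's median peak height (SD, n = 2). Lck, the kinase bound to CD4 and CD8 (chromosome 4, 129548344 to 129573641), stood at 10.4 ± 0.984. Lat, the adaptor of receptor signalling, stood at 10.4 ± 1.52, Cd8a at 9.71 ± 0.0113, Cd3e at 6.55 ± 2.33 and Cd4 at 3.21 ± 1.97 (n = 2 each). T-lineage transcription factors had promoter peaks in 20 of 20 members in both replicates. Among them, Sox4 stood at 14.7 ± 1.83, Ets1, a factor of lymphoid development, at 14.1 ± 1.58 and Satb1, a chromatin organiser, at 11.7 ± 0.225 (n = 2 each). Genes of the pre-T-cell receptor and V(D)J recombination had them in 14 of 15 members, among them the recombinase genes Rag1 at 8.38 ± 1.9 and Rag2 at 7.25 ± 1.60 (n = 2 each). The exception was Erg, a transcription factor of early progenitors, which had no promoter peak within 500 bp and a height of 2.30 within 1 kb. The median peak heights were 0.625 and 0.828, so the SDs given here also carry the difference between these medians. Deposited heights of Rag1 were 6.08 and 5.83, against 9.72 and 7.04 times the median. Those of Cd8b1 were 6.94 and 9.01, against 11.1 and 10.9 times the median.

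Against 63.4% of all 21938 protein-coding genes in replicate 1 and 57.8% in replicate 2, these lists were higher in 2 of 2 replicates by the two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists. The adjusted p was 0.00086 and 0.00017 for the receptor list and for the transcription factors, and 0.041 and 0.016 for the pre-receptor list. The call of the pre-receptor list was lost on autosomes alone (adjusted exact p = 0.063 in replicate 1), where the list stood 31.4 percentage points above other genes, against 32.8 over all chromosomes (means of the replicates). Genes expressed in mature and emigrating T cells, such as Klf2 (5.87 ± 0.290), which directs exit from the thymus, had promoter peaks in 13 of 15 members in both replicates and missed the threshold over all genes (adjusted exact p = 0.11 and 0.051). Cd40lg and Itgae had none.

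**Figure D2:**
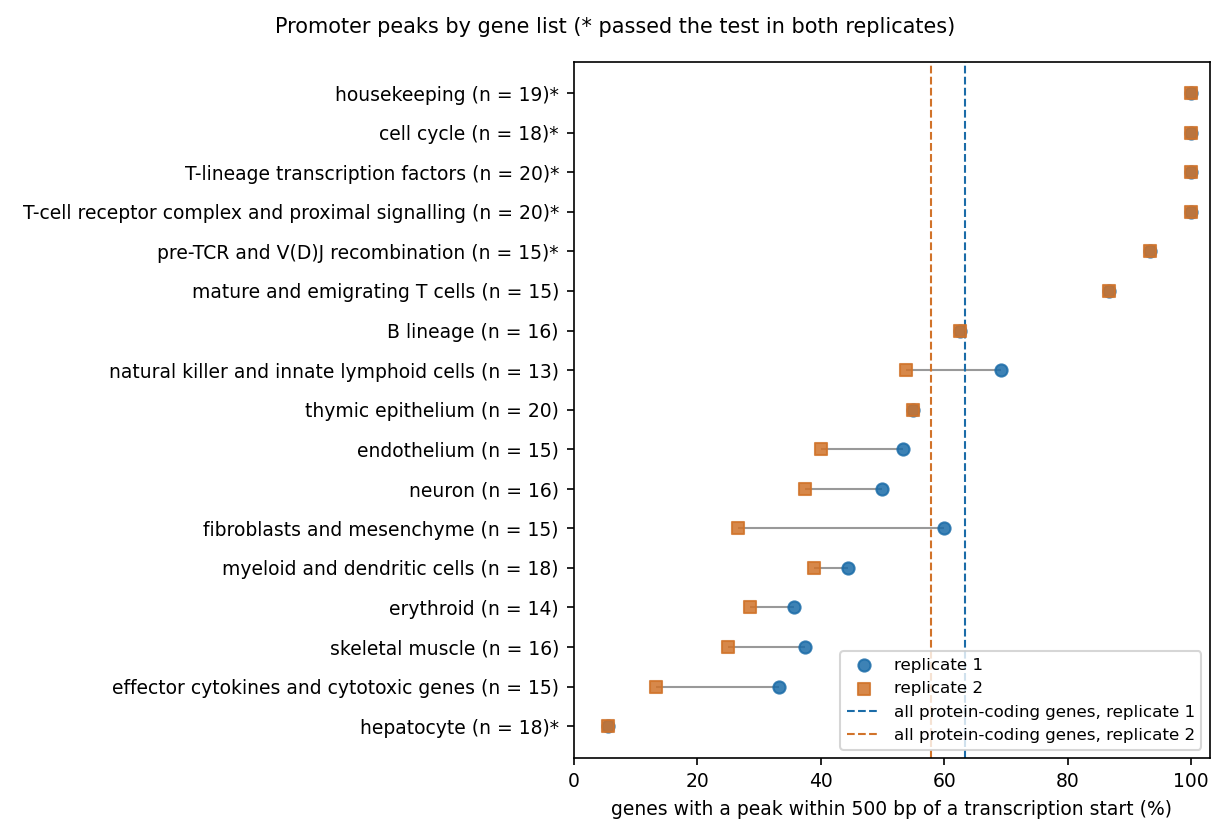
Share of the genes of each list with a peak within 500 bp of a transcription start (%, horizontal axis) in replicate 1 (circles) and replicate 2 (squares), with the number of genes per list and the share over all protein-coding genes as dashed lines. The receptor, T-lineage transcription factor, cell cycle and housekeeping lists stood at 100%, and the hepatocyte list at 5.56%, in both replicates.

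Genes of all dividing or living cells also had open promoters. Cell cycle genes had promoter peaks in 18 of 18 members, such as the replication helicase genes Mcm5 (19.7 ± 6.01) and Mcm2 (17.7 ± 5.34, n = 2 each), and housekeeping genes in 19 of 19, such as Rplp0 (24.3 ± 8.57) and Actb (23.1 ± 1.75), in both replicates. Of the genes of hepatocytes, cells of the liver, 1 of 18 had a promoter peak. This was Ahsg, at 0.331 ± 0.0361 times the median, which was not in the stricter peak file. Alb, the albumin gene, Apoa1 and Apoa2 had none. The exact test placed the cell cycle list (adjusted p = 0.0011 and 0.00037) and the housekeeping list (0.00086 and 0.00024) higher and the hepatocyte list (7.6e-06 and 7.8e-05) lower in 2 of 2 replicates. Among the 11857 genes with CpG-poor promoters these 3 calls were lost (adjusted exact p in replicates 1 and 2 of 0.14 and 0.077, 0.061 and 0.034, and 0.012 and 0.055), with 3 of 3 cell cycle, 4 of 4 housekeeping and 1 of 18 hepatocyte genes still carrying a peak. Of the other genes 38.3% and 31.6% carried one, and only 3 and 4 members of the cell cycle and housekeeping lists were left. The receptor list stood there at 20 of 20 members against 38.2% and 31.5% of the other genes (7.6e-08 and 1.6e-09), and the mature T cell list passed in both replicates (0.014 and 0.0038).

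Genes of other cell types of the thymus had mixed promoters, and none of these lists passed the test in both replicates. B-lineage genes had promoter peaks in 10 of 16 members in either replicate (adjusted exact p = 1.0 and 0.82), with Vpreb1, a surrogate light chain, at 6.65 ± 0.439 and none at Cd79a or Fcer2a. Thymic epithelium had them in 11 of 20 in both (0.59 and 0.82). Among these were Ccl25, the chemokine that draws progenitors (10.6 ± 2.71), and Aire, which drives the display of tissue antigens (6.84 ± 2.10). Foxn1, the master regulator of this epithelium, had none. A peak within 500 bp of the starts of neighbouring genes counted for each of them, and which gene it belongs to was not tested. Natural killer and innate lymphoid genes had them in 9 and 7 of 13 (0.84 and 0.82), led by Id2 (13 ± 2.84). Myeloid and dendritic genes had them in 8 and 7 of 18 (0.22 and 0.20), led by Fcgr3 (3.49 ± 0.559), and endothelial genes in 8 and 6 of 15 (0.56 and 0.24), led by Pecam1 (4.75 ± 3.31). Erythroid genes had them in 5 and 4 of 14 (0.091 and 0.051), with Tfrc, the transferrin receptor, at 16.8 ± 0.255, Gata1 at 1.23 ± 0.615 and none at Hba-a1. Neuronal genes had them in 8 and 6 of 16 (0.43 and 0.18), led by Syp (5.01 ± 1.88).

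Effector cytokine and cytotoxic genes had promoter peaks in 5 of 15 members in replicate 1 and 2 of 15 in replicate 2. The latter were Prf1, which encodes perforin (4.01 ± 1.35), and Fasl (1.93 ± 0.950), while Gzmb, Gzmk and Il10 had none in either replicate. Skeletal muscle genes had them in 6 and 4 of 16, led by Mylpf (10.1 ± 1.01), and genes of fibroblasts and mesenchyme in 9 and 4 of 15, led by Pdgfra (3.60 ± 1.21) and Col1a1 (3.53 ± 2.06). These 3 lists missed the threshold in replicate 1 (adjusted exact p = 0.068, 0.082 and 0.84) and were lower in replicate 2 alone (0.0022, 0.022 and 0.034). With equal numbers of peaks in the replicates, the effector list (0.016 and 0.0022) and the muscle list (0.0099 and 0.022) were lower in both, as they were in the upper part of the peaks by height. The effector list was also lower in both in the stricter peak file (0.036 and 0.0052) and on autosomes alone (0.041 and 0.0010), and neither list was called with a window of 1 kb (0.11 and 0.00099 for effector, 0.19 and 0.19 for muscle genes). Nearly all members of the effector and muscle lists have CpG-poor promoters. Among such genes, effector genes stood at 33.3% and 13.3% against 38.3% and 31.7% of the others (adjusted exact p = 0.90 and 0.29), and muscle genes at 33.3% and 20% (0.90 and 0.64).

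Distal peaks, over 1 kb from any transcription start and assigned to the nearest one within 100 kb, were dense around genes of the T lineage. T-lineage transcription factors had a mean of 37.9 distal peaks per gene in replicate 1 and 17.9 in replicate 2 (27.9 ± 14.1, SD, n = 2), against 7.09 and 2.95 in random lists matched on the length of sequence a gene could collect peaks from. The receptor list had 21.2 and 8.75 (15 ± 8.80) against 4.25 and 1.89. The pre-receptor list had 20.3 and 10.0 (15.1 ± 7.26) against 5.24 and 2.20, and the mature T cell list 15.5 and 5.73 (10.6 ± 6.88) against 4.74 and 2.12. Ets1 (chromosome 9, 32636221 to 32757820), had 97 distal peaks in replicate 1 and 41 in replicate 2. Satb1 had 63 and 37, Sox4 53 and 22, Tcf7, which specifies the T lineage (chromosome 11, 52252371 to 52283014), 47 and 52, and Bcl11b, which commits cells to it (chromosome 12, 107910403 to 108003602), 41 and 17. Of the replicate 1 distal peaks of Satb1, only 13 were overlapped by replicate 2, against 33 at Ets1 and 23 at Sox4. Cd8a had 42 and 13 and its neighbour Cd8b1 31 and 10, while Rag1 had 15 and 0 and Rag2 2 and 0. Overlapping peaks of a library were each counted, so these are numbers of peak calls and not of separate regions. Near Cd8b1, for example, replicate 1 peaks at 71323641 to 71324580 and 71323641 to 71324820 overlapped. No list was recounted over joined regions.

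All 4 lists were higher in 2 of 2 replicates by two-sided permutation against 10000 random lists. The permutation p was 0.0002 in each, the smallest they can give, except for the mature T cell list in replicate 2 (permutation p = 0.0052). The adjusted values were 0.00085 in replicate 1 and 0.0011 in replicate 2, or 0.022 for that exception. The other 13 lists were not called in both replicates. Natural killer and innate lymphoid genes (9.62 and 4.15 per gene, adjusted permutation p = 0.033 and 0.11) passed without replicate 2, and myeloid and dendritic genes (4.83 and 3.94, 0.38 and 0.035) without replicate 1. The latter rested on Itgam, the integrin of macrophages, with 16 and 37 distal peaks, of which 23 in replicate 2 belonged to a run of very low peaks. Without the windows of 100 kb that held such runs the unadjusted permutation p of the myeloid list was 0.53 and 0.47. In that setting the T-lineage transcription factors had 36.35 and 16.3 distal peaks per gene and the receptor list 20 and 7.6. All 4 T-lineage lists were still called there.

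Among the remaining lists, the means per gene were 6.33 and 2.20 for effector genes (adjusted permutation p = 0.30 and 0.85) and 3.69 and 1.56 for the B lineage (0.95 and 0.96). They were 4.25 and 1.85 for thymic epithelium (0.75 and 0.93) and 5.73 and 2.87 for endothelium (0.95 and 0.85). Fibroblast genes had 3.73 and 1.27 (0.32 and 0.21), erythroid genes 1.79 and 0.429 (0.74 and 0.24), cell cycle genes 3.0 and 1.28 (0.71 and 0.93) and housekeeping genes 5.00 and 2.79 (0.15 and 0.098). Hepatocyte genes had 2.22 and 0.722 (0.38 and 0.21), neuronal genes 5.63 and 2.06 (0.95 and 0.96) and muscle genes 1.94 and 1.06 (0.74 and 0.96).

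**Figure D3:**
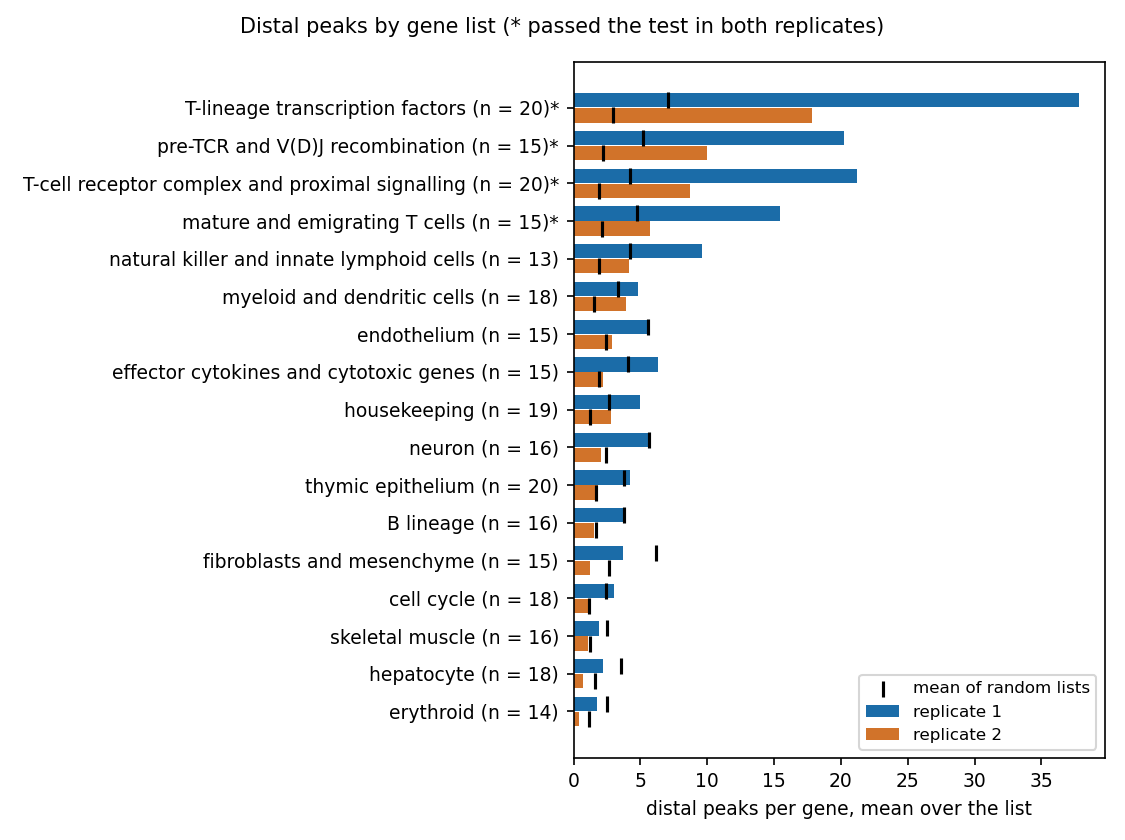
Mean number of distal peaks per gene (horizontal axis) for each list in replicate 1 (upper bars) and replicate 2 (lower bars), with the mean of 10000 matched random lists as black marks and the number of genes per list. The T-lineage transcription factors stood at 37.9 and 17.9, against 7.09 and 2.95 in random lists.

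Over all genes, the most distal peaks shared by both replicates lay at Gse1 (44; chromosome 8, 120228456 to 120581390), Bcor, a corepressor (41; chromosome X, 12036740 to 12160355), and Prex1 (38; chromosome 2, 166566342 to 166713832). Next were Mvb12b (36) and Zmiz1 (34; chromosome 14, 25459185 to 25666743). Ets1 and Tcf7 followed with 33 each and Cd2, an adhesion receptor of T cells (chromosome 3, 101275899 to 101287939), with 32. The first 20 genes also held the transcription factors Foxp1, which keeps T cells quiescent, and Bach2, which restrains effector genes.

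**Figure D4:**
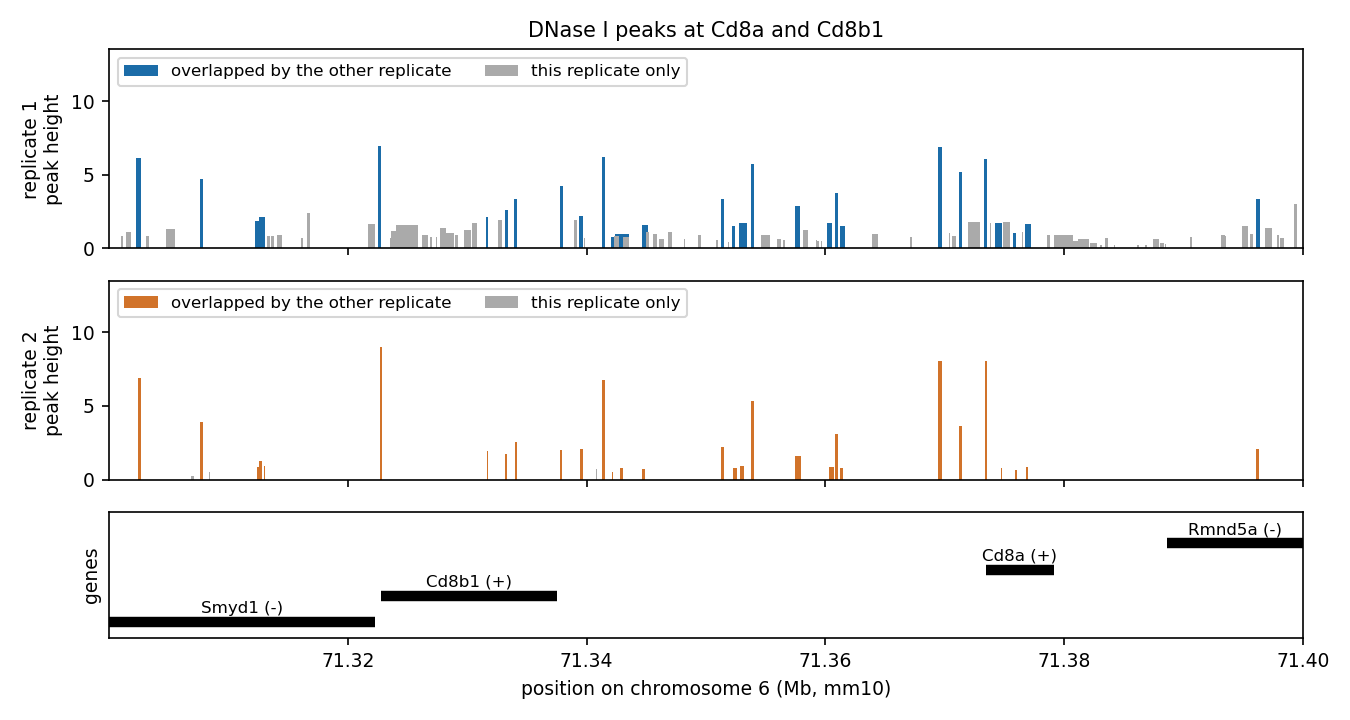
Peaks of replicate 1 (top) and replicate 2 (middle) at the CD8 genes, chromosome 6, 71300001 to 71400000 (mm10, horizontal axis in Mb), drawn from start to end with the deposited height (vertical axis), in colour where the other replicate overlapped them and in grey otherwise, above the protein-coding genes (bottom). Replicate 1 had 112 peaks in this window, some of which overlapped one another, and replicate 2 had 34. Of the replicate 1 peaks, 30 were overlapped by replicate 2.

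The genes whose promoter peak was seen in replicate 1 alone were compared with the lists, to ask whether they belonged to a given cell type of the tissue. They numbered 1357, against 132 with a promoter peak in replicate 2 alone, and with equal numbers of peaks these counts turned to 207 and 668. No member of the 4 T-lineage lists was among the 1357 (0 of 20, 0 of 14, 0 of 20 and 0 of 13 members with a replicate 1 peak). None of these lists was called (adjusted exact p = 0.43, 0.57, 0.43 and 0.71). The absence cannot be told from the share of other genes, since an emptied receptor list was called in 0% of simulations. Genes of fibroblasts and mesenchyme were among the 1357 in 5 of 9 members, against 9.73% of other genes. These were Acta2, smooth muscle actin, at 1.40 times the median height, Twist1 at 0.352, Fbn1 at 0.324, Col1a2 at 0.250 and Tcf21 at 0.213, named after their values were seen. Effector genes stood at 3 of 5, natural killer and innate lymphoid genes at 2 of 9, and endothelium and neuron at 2 of 8 each. Muscle genes stood at 2 of 6, the B lineage at 1 of 10, myeloid genes at 1 of 8 and erythroid genes at 1 of 5. Epithelium (0 of 11), cell cycle (0 of 18), housekeeping (0 of 19) and hepatocyte genes (0 of 1) had none.

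The fibroblast list passed the two-sided Fisher's exact test over 13904 genes (exact p = 0.00079, adjusted 0.013), in the 1 comparison that these 2 libraries allow, and the effector list did not (0.0080, adjusted 0.068). The list stood 45.8 percentage points above other genes. The call ended with equal numbers of peaks in the replicates (18.3 points, adjusted exact p = 0.61), in the stricter peak file (9.91 points, 0.50) and, with fewer members and a difference of 38.1 points, among CpG-poor promoters (0.24). The effector list passed with a promoter window of 1 kb (adjusted exact p = 0.012), and the myeloid (0.048), natural killer (0.0498) and neuronal lists (0.0498) in the stricter peak file.

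Footprints, short stretches inside accessible regions where a bound protein shields the DNA from DNase I, numbered 375374 in replicate 1 and 210014 in replicate 2, with a median width of 10 bp in both. In the 54596 regions accessible in both animals the numbers were 212090 and 171133, a ratio of 1.24 against 1.79 over all footprints. Within these regions 51% of replicate 1 footprints and 65.4% of replicate 2 footprints were overlapped by one of the other animal, against at most 26.5% and 32.8% in 100 circular shifts. Of the footprints, 79.6% and 80.8% lay inside peaks. No test was run on these shares, and requiring an overlap of 50% of both footprints gave 36.5% and 45.2%.

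Which proteins bind in these footprints was asked with 21 consensus sequences. The consensus of CTCF, the insulator protein, was in 1.38% of replicate 1 and 1.87% of replicate 2 footprints. It was in 0.0195% and 0.0178% of control segments of the same peaks, which gave odds ratios of 70.9 and 106. CREB (TGACGTCA) had odds ratios of 20.8 and 27, and NRF1, a regulator of mitochondrial genes, 15.9 and 13.3. Of the factors of thymocyte development, the TCF/LEF consensus, bound by Tcf7 and Lef1, was in 0.705% and 0.451% of footprints with odds ratios of 2.51 and 2.00. The RUNX consensus was in 0.714% and 0.503% with 2.53 and 1.72. These 5 motifs were more frequent in footprints in 2 of 2 replicates by the two-sided Fisher's exact test and exceeded each of the 20 shuffled versions of their consensus. The adjusted exact p was 3.2e-117 and 1.8e-20 for RUNX and 1.7e-114 and 2.1e-27 for TCF/LEF. The size of the odds ratios depended on the setting. That of CTCF was 313 and 302 without the extension of 5 bp, 26.3 and 85.2 with controls at least 50 bp from the peak edge, 33.1 and 38.4 in promoter peaks and 100.4 and 220.3 in distal peaks. That of CREB was 49.3 and 41.5 without the extension and 11.4 and 11.1 with controls away from the edge, and that of NRF1 36.9 and 37.3, and 8.67 and 12.3. The RUNX call was lost in promoter peaks (1.78 and 1.15). It was also lost without extension, and the NRF1 call in distal peaks, where the odds ratios were 2.45 and 1.53, and 13 and 19.9, and single shuffled versions reached up to 3.10 and 31.

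The other 16 motifs were not called in both replicates. SP/KLF (7.22 and 6.83) and ETS (1.91 and 1.60) had odds ratios above 1. Shuffled versions reached up to 7.06 and 7.22 for SP/KLF, above its value in replicate 2, and up to 1.99 and 2.01 for ETS, above its value in both replicates. YY1 stood at 1.56 and 1.47, ROR at 1.52 and 1.17, IRF at 1.43 and 0.995, NFY at 1.17 and 1.33, and HNF4 at 1.36 and 0.951. MEF2 stood at 1.39 and 0.830, NF-kB at 1.08 and 0.946 and the E proteins at 1.05 and 1.12. IKZF (0.939 and 0.872), AP-1 (0.851 and 0.703), MYB (0.765 and 0.730), GATA (0.723 and 0.584) and OCT (0.736 and 0.447) lay below 1, and HNF1, a hepatocyte factor, was in 0 footprints of either replicate. Without replicate 2, the calls were 8, with SP/KLF (log2 odds ratio 2.85), YY1 (0.65) and IRF (0.51) added, and without replicate 1 NFY (0.41) was added. YY1 was also called with control segments from another seed (0.68), with control segments away from peak edges (0.81) and in distal peaks (0.96), and ETS in promoter peaks (1.05). Footprints had a GC content of 56.0% and 62.0%, against 52.1% and 56.5% in control segments.

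**Figure D5:**
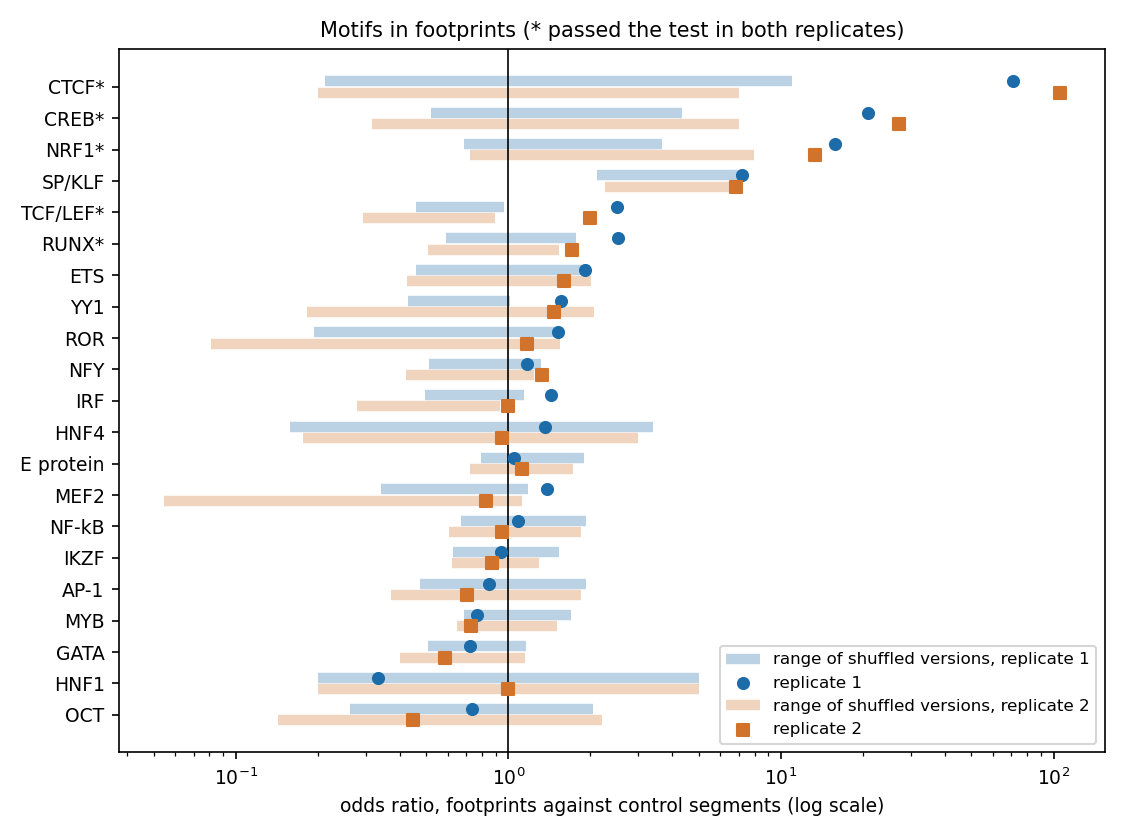
Odds ratio of each consensus in footprints against control segments of the same peaks (log scale, horizontal axis) in replicate 1 (circles) and replicate 2 (squares), over the range of 20 shuffled versions of the consensus (shaded bars). CTCF lay at 70.9 and 106, and 0.5 was added to each count, so that HNF1, found in 0 footprints, could be drawn.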

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

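The tests of GC recovery and of the share of T-lineage cells were chosen only after the results they bear on were seen.

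Peaks on chromosome Y drew attention because the mice were female and no named result lies on this chromosome. Replicate 1 had 54 and replicate 2 had 54 such peaks, with median heights of 0.188 and 0.252. DNA of male cells is argued against by the promoters of Ddx3y, Kdm5d, Uty and Eif2s3y, single-copy genes of males, of which 0 of 4 carried a peak, although 1 peak lay in the body of Ddx3y in replicate 1 and 1 in that of Uty in replicate 2. Sequence shared with other chromosomes may account for part of the peaks, since 67.6% matched another chromosome, against 2.55% of autosomal peaks, and 87.0% and 88.9% matched some other place, chromosome Y included. Of the 54 peaks each, 28 in replicate 1 and 37 in replicate 2 matched the X chromosome. Past 90 Mb of the 91.7 Mb of chromosome Y lay 30 and 22 of the peaks. The share of 67.6% lay between the bounds set for and against shared sequence. Whether shared sequence accounts for all of the peaks stays open, and no other explanation was tested.

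Replicate 1 had 1.9 times the peaks of replicate 2. The height steps of the libraries had a ratio of 1.00, which leaves open whether their depths were equal. A smaller share of T-lineage cells in replicate 2 was asked with shared distal peaks near T-lineage genes. Their log2 height ratio of replicate 2 to replicate 1 lay 0.11 above that of other shared distal peaks of equal height and GC content (random gene sets, -0.09 to 0.07). This cannot decide the question, since only peaks called in both libraries entered, and the other peaks may also be open in T-lineage cells. Weaker enrichment over background in replicate 2 was left undecided, since the share of replicate 1 peaks found in replicate 2 was 96.9 percentage points higher among the highest than among the lowest 10% by height, but the reverse comparison also gave 65.1 points, so that such a gradient arises whichever library is weaker. A difference in the recovery of GC-rich and GC-poor sequence may contribute, since at equal height the GC-richest 20% of distal peaks were found 34.5 points more often than the GC-poorest, on average over height bins 3 to 8 of 10 (12.3 to 52.9), and other differences between the animals were not tested.

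Very low peaks of replicate 2 lay in runs, with 929 of its 1345 lowest peaks (the lowest 2% by height) in 82 windows of 100 kb, against 28 of 2582 in 4 windows of replicate 1. The largest runs were at chromosome 3, 3000001 to 3100000, with 52 low peaks, chromosome 4, 3000001 to 3100000, with 33, and chromosome 15, 75500001 to 75600000, at Gpihbp1 and Ly6h, with 29. More open chromatin or more copies of these regions in replicate 2 was asked with 618 pairs of shared peaks inside the windows. Their median log2 height ratio of replicate 2 to replicate 1 lay at -0.11 relative to other shared peaks (95% interval -0.23 to -0.03). This argues against it only where shared peaks lay. Of the low peaks in runs, 1.83% were overlapped by replicate 1, and the windows on chromosomes 3 and 4 held 0 and 1 replicate 1 peaks. The question stays open for the low peaks themselves and for those windows. A calling threshold that is lower in some regions is a candidate explanation, since low peaks inside the runs were kept in the stricter file 28.5 percentage points more often than low peaks elsewhere (61.5% against 32.9%). No biological explanation besides copy number and openness was tested.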

How the results depend on the processing

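The alternatives without windows holding runs of low peaks, and CpG-poor promoters for peaks seen in replicate 1 alone, were chosen after seeing the data. No paired analysis was possible because there is 1 group. Of the 17 lists, 6 were called for promoter peaks, and 6 to 9 without 1 replicate, and 4 for distal peaks in each of the planned and added settings but 5 without replicate 1 and 5 without replicate 2. The upper part of the peaks by height left a mean of 50734 peaks per replicate by its construction, with a height correlation of 0.890 and a promoter share of 41.5%, and reciprocal overlap gave a height correlation of 0.904 and a footprint overlap of 40.9%. For peaks seen in replicate 1 alone, 1 list was called, 2 with a promoter window of 1 kb, 0 with equal peak numbers, 3 in the stricter file and 0 among CpG-poor promoters. Called motifs numbered 5, and 6 without replicate 1 to 8 without replicate 2. Leaving out 1 replicate gave 69798 to 132737 peaks, 24.6% to 37.9% in promoters and 210014 to 375374 footprints. A further 45 values changed sign, and none of them was called in the setting that changed its sign or in the main one. IRF, among these, was called without replicate 2 (0.51). For promoter peaks (percentage points between a list and other genes) they were natural killer genes at -0.813 and neuron at 6.40 with 1 kb. Next were the B lineage at -6.02 and natural killer genes at -6.74 in the upper part by height, -0.426 and -2.83 in the stricter file. Others were epithelium at 18.4, fibroblasts at 3.51 and endothelium at 0.0418 among CpG-poor promoters, and natural killer genes at -0.381 on autosomes. Without 1 replicate the ranges were -3.95 to 5.86 for natural killer genes and -0.879 to 4.71 for the B lineage. For distal peaks (log2) they were neuron at 0.0222 with 50 kb, the B lineage at 0.17 and neuron at 0.16 in the upper part, the B lineage at 0.00168 with equal peak numbers, and cell cycle at -0.42 and neuron at 0.38 without matching. For peaks seen in replicate 1 alone (percentage points) they were the B lineage at -0.351 and hepatocyte at 39.7 with 1 kb, myeloid at -1.70, endothelium, erythroid, neuron and muscle at -1.69 with equal numbers. Others were epithelium at 17.2 and erythroid at -10.1 in the stricter file, and the B lineage at -6.65 and erythroid at -19.2 among CpG-poor promoters. For motifs (log2 odds ratio) they were ROR at -0.44, NFY at -0.0283, IRF at -0.22 and MEF2 at -0.14 without extension. Next were E protein at -0.22, NFY at -0.20, NF-kB at -0.0185 and MEF2 at -0.28 with controls away from the edge. In subsets they were HNF4 at -0.16 and MEF2 at -0.21 in distal peaks, and E protein at -0.46 and NF-kB at -0.24 in promoter peaks. Without 1 replicate the ranges were -0.0804 to 0.12 for NF-kB, -0.00738 to 0.51 for IRF, -0.0722 to 0.45 for HNF4 and -0.27 to 0.47 for MEF2. Except where given, the cause was not tested. Among the other values for single lists, motifs and named genes with both replicates in use, 653 kept their direction and side of the threshold or moved by less than the spread, 15 came past the threshold, 10 fell short of it and 13 moved by more than the spread. The number of reads behind each peak was not read from the files, and peaks or footprints seen in 1 replicate alone are bounded by the calls of the other, so their absence was not detectable from these lists.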

Other observations

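The antigen receptor loci differed in how many peaks they held. Tcra and Tcrd (chromosome 14, 52427928 to 54224206) had 134 peaks per Mb in replicate 1 and 77.4 in replicate 2, and Tcrb (chromosome 6, 40891229 to 41558452) had 148 and 68.9, against 48.7 and 25.6 over the genome. The immunoglobulin heavy chain locus Igh (chromosome 12, 113254830 to 116010093) had 87.5 and 36.3, while the light chain loci Igk (9.77 and 3.15) and Igl (5.02 and 5.02) and the Tcrg locus (37.9 and 22.7) lay below the genome. The values of Tcrg rest on 5 and 3 peaks in 0.132 Mb, the extent of 5 segments found by name. Those of Igl rest on 1 and 1 peaks in 0.199 Mb. These counts are too small to rank either locus against the genome. Among the 10 windows of 100 kb with the most shared peaks were those of Tcf7 (44 shared peaks; chromosome 11, 52200001 to 52300000), Cd2 (34), a cluster of histone genes (31; chromosome 13, 23500001 to 23600000), the CD8 genes (30) and the cyclin gene Ccnd3 (29; chromosome 17, 47500001 to 47600000), against a median of 3 over 12370 windows with any. These loci, and the families and motifs given next, were chosen without a rule fixed beforehand and were not tested.

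Gene families differed in their promoters. Promoter peaks were found in 80 of 83 ribosomal protein genes in either replicate, and in 58 of 67 replication-dependent histone genes in either replicate. Zinc finger genes named Zfp had them in 335 and 320 of 394, genes of the major histocompatibility complex in 20 and 19 of 34, interferon-induced GTPases in 11 and 9 of 13 and C-C chemokine receptors in 8 and 6 of 16. Olfactory receptors had them in 30 and 8 of 1135, vomeronasal receptors in 3 and 1 of 329, Hox genes in 12 and 9 of 39, killer lectin-like receptors in 5 and 1 of 26 and clustered protocadherins in 21 and 4 of 57.

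The CTCF consensus was in 11.1% of the 35629 shared distal peaks, 3.93% of the 64429 distal peaks of replicate 1 alone and 0.247% of the 7281 of replicate 2 alone, against 0.230%, 0.152% and 0.110% in sequence 2 kb away. The ETS consensus was in 10.8%, 10.0% and 3.71% (3.31%, 3.20% and 3.42% away) and the RUNX consensus in 6.21%, 5.79% and 2.23% (2.45%, 2.45% and 2.46% away). The E protein consensus was in 32.4%, 22.5% and 23.8% (15.6%, 14.2% and 14.2% away).

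Among the highest peaks of both replicates, sequence present in several copies is a candidate explanation for some. Of the 10 peaks, 4 matched another place in the genome, between the bounds set for and against it beforehand. Of 1000 random autosomal peaks per replicate, 3.7% and 5.1% did. For the set of 10 this explanation cannot be told apart from unique sequence that is highly accessible. The search covered the assembly alone, so copies that it lacks would not show, and peaks without a match need not be unique. The peaks without a match included the promoters of Dnpep, Mplkip, Fzr1 and Ing2.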
